A study of Homo sapiens with 8 samples.

How the data were processed

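The series holds 8 arrays of total RNA from xenograft tumours. Per the labels' protocols, 1000000 cells were injected under the skin of nude mice aged 5 weeks, tumours were collected once at least 5 mm across, and biotin-labelled cRNA was made from 100 ng of total RNA. The arrays fall into 2 groups of 4, long and short telomeres. They were paired by the cell line and the mark cre in their titles. In each group the titles name HBC4 and MKN74 on 1 array each and PC-3 on 2, 1 of them with cre attached to basal hTERT, and the pair so marked is called PC-3/cre here for short. Nothing states how many mice or tumours stand behind an array, and both PC-3 pairs carry the name of the same line, so the 4 pairs stand for 3 lines. What cre stands for is not stated in the titles.

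The deposited values were made with RMA, per the submitters' processing notes, and were read here as log2 values. The background, normalization and summary settings, the software and its version are not given in the sources used here. The values show that each probe set was centred on its own median over the 8 arrays (largest absolute median 5e-07). Levels, detection calls and signal over background are therefore not known, whereas differences between arrays within a probe set are intact. That the log base is 2 was taken from the use of RMA and the widest range of a probe set (10.9), and is not stated.

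Of 54675 probe sets, 41097 were listed with 1 gene symbol, 1801 with several and 11777 with none here, and 62 were controls. Symbols were updated through the gene identifier with a RefSeq gene table, which held 99.9% of the identifiers. The 41089 probe sets used gave 19775 genes, 10523 of them with more than 1 probe set. Probe sets with several or no symbols were left out because they name no single gene. Some members of the fixed gene lists are not analysed here, and some are not reported here.

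The filter and the choice of probe set fixed before the data were examined could not be applied to centred values. A filter on the 40th percentile of the mean was dropped, and the probe set with the highest mean was replaced by the one whose 4 pair means had the largest SD. A change in the long-telomere array of only some pairs also moves their pair means. This SD can therefore favour probe sets whose ratio of long over short telomeres differs between pairs or lines. For TERT it took the probe set with the larger ratios. With the mean of all probe sets of a gene, which selects none, limma gave 8 genes for long against short telomeres and 73 for the difference between lines. The filters on spread and the matched random lists rest on the same SD. The replacement was chosen after the values, including both TERT probe sets, had been seen. Random lists were matched on the same SD, in 10 classes, in place of the mean level.

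Long and short telomeres were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the pair as a fixed block, 3 residual degrees of freedom (6.18 with the moderated prior) and Benjamini-Hochberg adjustment over 19775 genes at 0.05. The pairing comes from the titles. The deviations of the 2 arrays of a pair from their group means correlated at 0.872 (PC-3), 0.748 (PC-3/cre), 0.921 (HBC4) and 0.874 (MKN74), which any arrays of 1 line would show. They do not tell the PC-3 pair from the PC-3/cre pair, whose arrays were each nearest to an array of the other pair (0.850 and 0.798, against 0.642 and 0.450 within the pairs). The contrast between the PC-3 pairs and the others used the same block with separate effects. Flipping the direction of 4 pairs cannot give a two-sided p below 0.125, so no exact test of a single gene could reach 0.05.

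Gene lists (16, fixed before the data were examined) were tested with camera (preset correlation 0.01), camera with an estimated correlation and fry, all in limma, and each pair's list median was placed among 10000 random lists. The random lists were drawn without regard to how genes vary together, and each arm is 1 array, so these placings describe a pair and do not test it. Lists added after the data were seen are epidermal markers and 3 lists around interferon signalling. Genes near chromosome ends were taken from the order of genes in the RefSeq table, 20 per end, without the p ends of 5 acrocentric chromosomes and without the Y chromosome. Counts of genes at least 1.5-fold changed in all 4 pairs and 2-fold changed in each pair carry no p-value. The 1.5-fold count was set beside other sign patterns of the pairs. Fisher's exact test was used only for the share of the interferon list among its lower genes.

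Genes are named by a rule fixed beforehand. It took a short set of genes always, the 10 genes with the largest change per direction past the threshold (filled to 10 from genes changed 1.5-fold in all pairs where fewer than 5 passed), the 4 members of each list with the largest moderated statistic, the 4 largest changes per direction and pair, and the 4 smallest p-values per direction between lines. Not every gene taken by the rule is printed, and genes outside it are named as chosen later or as members of a small count or of a contrast with a list.

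The scripts were tested on simulated data drawn from the real pair means and spreads of the 19775 genes, with known changes put into a random set of them. For long against short telomeres, limma recovered 24% of genes changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 4-fold, and called 16 unchanged genes. Each of these changes had the same size in every pair, and the simulated genes varied independently of each other. The rates therefore do not carry over to genes that differ more between pairs. In the real data IFIT1 and TERT had mean changes of 5.92-fold and 7.83-fold without passing (limma adjusted p = 0.105 and 0.494). For the contrast between PC-3 and the other lines it recovered 4% at 2-fold and 78% at 4-fold, with 7 unchanged genes called. The 1.5-fold count in all 4 pairs recovered 68% of genes changed 2-fold and counted 2 unchanged genes. Alternatives covered the choice and averaging of probe sets, centring of arrays, filters on the spread of pair means, the block, the moderation, the list test, the fold bounds and leaving out each pair.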

Results

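Gene expression was measured on human oligonucleotide arrays in subcutaneous xenograft tumours, with 8 arrays in total. The tumours grew in nude mice from 3 established human carcinoma cell lines, namely PC-3 (prostate), HBC4 (breast) and MKN74 (gastric). Each of 4 arrays from telomere-elongated cells (long telomeres) had a control array of the same line (short telomeres), which gave 4 pairs called PC-3, PC-3/cre, HBC4 and MKN74 here (PC-3/cre being PC-3 arrays whose titles also hold the mark cre). The long-telomere cells of the PC-3, HBC4 and MKN74 pairs over-expressed hTERT, the catalytic subunit of telomerase, whereas both members of the PC-3/cre pair had basal hTERT. Every value below is a log2 ratio of long over short telomeres within a pair, or the mean of those ratios over the 4 pairs. Each arm of a pair held 1 array, the number of arrays limits the precision, and limma p-values of single genes measure the spread between 4 pairs from 3 lines. The p-values of camera with the preset correlation and of Fisher's exact test rest on genes as the units. They do not measure that spread, and their small size is not evidence from more pairs.

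The transcript of TERT was higher in the long-telomere array of each pair on the probe set used for it here. The difference was 5.85-fold in the PC-3 pair, 13.5-fold in the HBC4 pair and 27.3-fold in the MKN74 pair. It was 1.73-fold in the PC-3/cre pair, where the value of the long-telomere array (-0.46, relative to the median of all arrays) was close to that of the PC-3 short-telomere array (-0.48). The mean log2 ratio was 2.97 ± 1.71 (SD, n = 4 pairs), with a limma adjusted p of 0.494 because the pairs differed so much in size. The other TERT probe set gave -0.39, 0.55, 0.46 and -0.05 in the PC-3, PC-3/cre, HBC4 and MKN74 pairs. Whether either probe set lies in the part of the transcript that the introduced gene carries was not determined here.

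Tumours with long telomeres had lower levels of interferon-stimulated genes in every pair. The list fixed for this class had a median log2 ratio of -1.63, a 3.09-fold difference, and 42 of its 45 tested members were lower in all 4 pairs. Of these members, 42 fell when adjusted over the list alone, and 6 fell when adjusted over all genes. RSAD2, which encodes the antiviral protein viperin, fell by 2.88 ± 0.24 (SD, n = 4 pairs; limma adjusted p = 0.00539). The tetratricopeptide-repeat genes IFIT2 and IFIT3 had log2 ratios of -2.30 ± 0.22 and -2.15 ± 0.33 (limma adjusted p = 0.00861 and 0.0292). IFI44L had the lowest mean ratio of the list, -3.46 ± 0.81, followed by RSAD2 and by IFI44 at -2.77 ± 0.57, and the oligoadenylate synthetase gene OAS1 stood at -2.41 ± 0.50 (limma adjusted p = 0.0432, 0.0376 and 0.0379).

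The other members of the interferon list missed the threshold over all genes. The ubiquitin-like modifier ISG15 had a mean log2 ratio of -1.58 ± 0.43 (limma adjusted p = 0.104), and OAS3 had one of -1.51 ± 0.39 (limma adjusted p = 0.0948). The members that did not pass over the list alone were PLSCR1, RIGI and DHX58, with mean ratios of -1.08, -0.59 and -0.20. The list medians were -2.20 in the PC-3 pair, -1.89 in the PC-3/cre pair, -1.34 in the HBC4 pair and -1.12 in the MKN74 pair. In each pair the median lay below those of all 10000 random lists of the same size and spread. This placing is no test, since genes of the random lists need not vary together as those of this list can. The list passed camera with the preset correlation (adjusted p = 4.34e-60) and limma's fry test (adjusted p = 0.0222). It did not pass camera with the correlation estimated from these arrays (adjusted p = 0.113 with an estimated correlation of 0.219, against the preset 0.01).

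**Figure D1:**
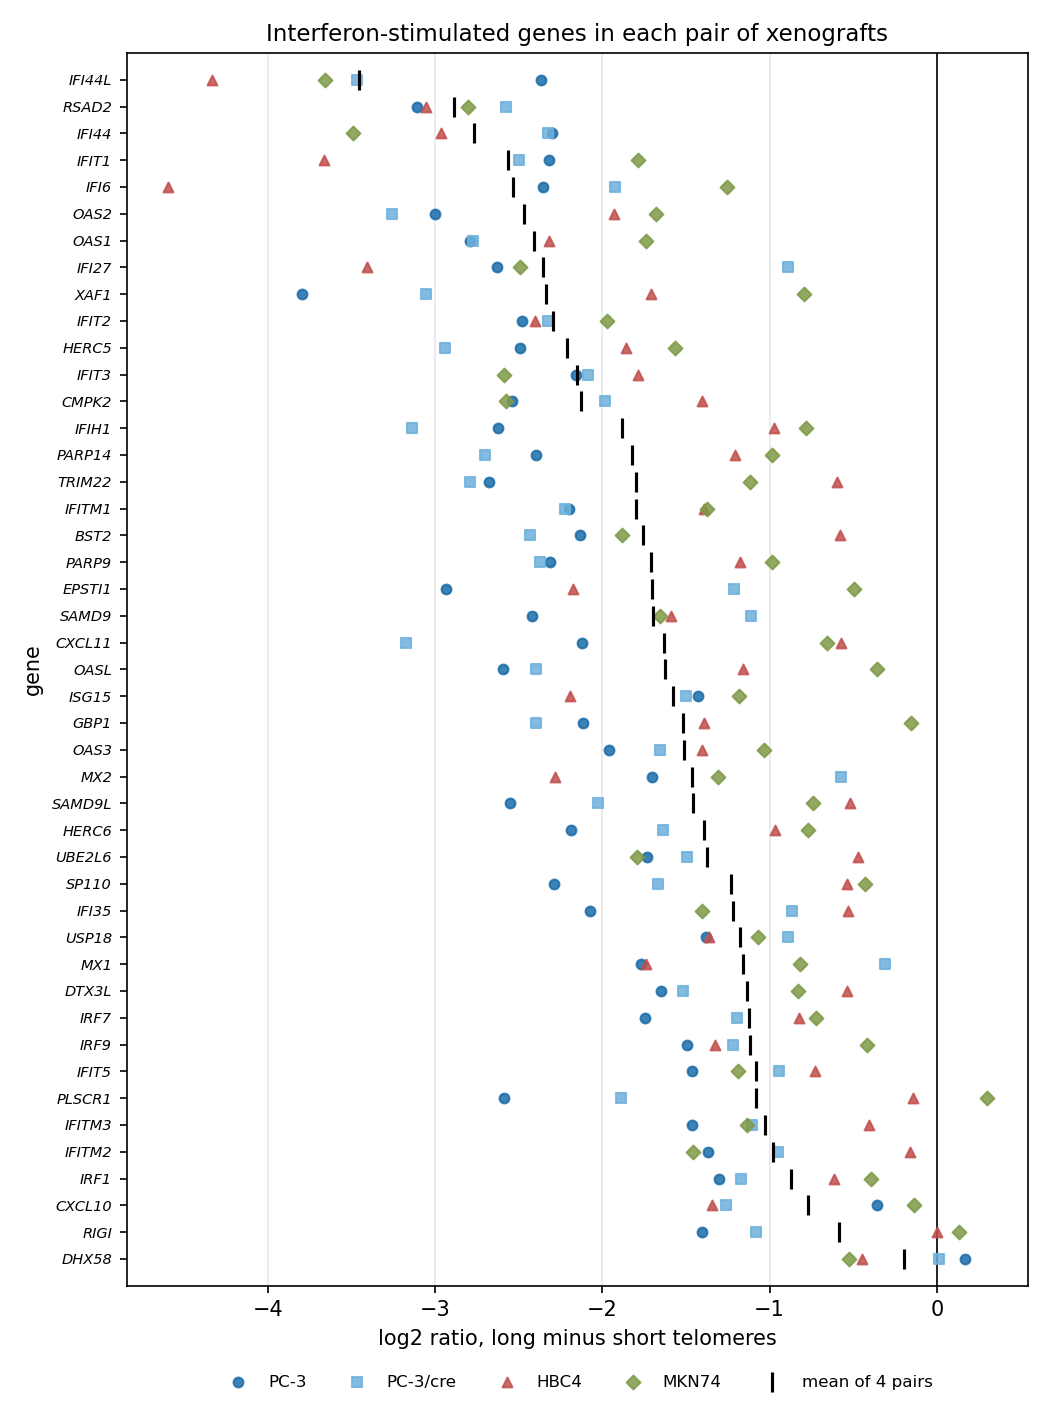
Log2 ratio of long over short telomeres (horizontal axis) for the 45 tested interferon-stimulated genes (vertical axis, ordered by the mean), with 1 symbol per pair of xenografts and a black bar for the mean of the 4 pairs. For 42 of the 45 genes all 4 symbols lie left of 0, and IFI44L has the lowest mean, -3.46.

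Across the 19775 genes tested, 9 passed a limma adjusted p of 0.05, of which 8 fell and 1 rose. The gene that rose was KRT14, a keratin of basal epidermal cells, at 1.21 ± 0.03 (SD, n = 4 pairs; limma adjusted p = 0.0376). Its call was lost whenever a pair was left out (limma adjusted p from 0.127 to 0.344) and with a trend in the moderation (limma adjusted p = 0.151). The lower genes outside the interferon list were HSH2D, an adaptor protein gene, at -1.26 ± 0.13 and CRACD, a regulator of actin capping, at -1.16 ± 0.14 (limma adjusted p = 0.0376 and 0.0432). The adhesion genes CDH1 and CDH2 and the intermediate filament gene VIM had mean ratios of -0.28 ± 1.21, -0.04 ± 0.35 and 0.07 ± 0.31, and none of them passed. CDH1, the epithelial cadherin, ranged from -2.00 in the PC-3/cre pair to 0.83 in the PC-3 pair. At an unadjusted limma p under 0.05 there were 670 higher and 874 lower genes. The count of 9 rested on all 4 pairs: it was 2 without the PC-3 pair, 1 without the PC-3/cre pair, 0 without the HBC4 pair and 3 without the MKN74 pair. It was 0 in limma with the pair as a random block (1437 genes at an unadjusted p under 0.05), so that the calls of these 9 genes depend on how the block enters the model. Most of them were kept with the cell line as the block in place of the pair. The count was also 0 in limma with no block for the pair (109 unadjusted), and 1 with the PC-3 pairs averaged into 1.

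A count that needs no estimate of the spread gave more genes. At least 1.5-fold changes in the same direction in all 4 pairs were seen for 50 genes, 43 lower and 7 higher with long telomeres. Of the 43 lower genes, 25 belonged to the interferon list, against 0.0979 by chance (Fisher's exact test, two-sided p = 1.18e-58; genes are not independent replicates). A further 3 belonged to the antigen presentation list, and 15 to neither. The lists were a fixed choice of genes, so a gene in neither may still be interferon-stimulated. Among these 15, chosen after their values were seen, were the lysosomal membrane gene LAMP3 (-2.00 ± 0.71), the helicase gene DDX60 (-1.87 ± 0.63) and RTP4 (-1.86 ± 0.87). BTN3A1, of the butyrophilin family, had a ratio of -0.99 ± 0.11 (limma adjusted p = 0.0789).

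The 7 genes at least 1.5-fold higher in all 4 pairs were TERT, KRT14, CLCA2, HPGD, S100A8, SFXN5 and PRKG1. CLCA2, a regulator of chloride conductance, had a mean log2 ratio of 1.46 ± 0.58, and HPGD, which encodes a prostaglandin-degrading dehydrogenase, one of 1.10 ± 0.46. The calcium-binding protein gene S100A8 had a ratio of 1.02 ± 0.26, the sideroflexin gene SFXN5 one of 0.77 ± 0.14, and the cGMP-dependent kinase gene PRKG1 one of 0.73 ± 0.14. Their limma adjusted p-values lay at 0.148 (S100A8), 0.151 (SFXN5), 0.204 (PRKG1), 0.27 (CLCA2) and 0.328 (HPGD). With 2-fold in every pair as the bound, the count was 21 genes, of which 20 were lower. The 1.5-fold count was 118 without the HBC4 pair and 117 without the MKN74 pair, where fewer pairs had to share a direction.

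Genes of antigen presentation were also lower with long telomeres. The list had a median log2 ratio of -0.41 over 27 tested members, and 13 of them fell when adjusted over the list alone, while 0 passed over all genes. Examples were the immunoproteasome subunit gene PSMB9 at -1.22 ± 0.30, the peptide transporter gene TAP1 at -0.93 ± 0.21, the class I transactivator gene NLRC5 at -0.92 ± 0.27 and HLA-B at -1.06 ± 0.43. The class II gene HLA-DRA, by comparison, had a ratio of -0.21 ± 0.50. Probe sets of the class I HLA genes can share sequence, so their values are not independent. The list passed camera (adjusted p = 5.06e-15) and fry (adjusted p = 0.0222), with an adjusted p = 0.113 with an estimated correlation.

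Inflammatory cytokines and NF-kB targets had a median log2 ratio of -0.33 over 32 tested members. By pair the medians were -0.32 (PC-3), -0.07 (PC-3/cre), -0.43 (HBC4) and -0.28 (MKN74). The PC-3/cre median was thus near 0 and lay above 19.5% of the random lists, against at most 0.02% in the other pairs. Over all 4 pairs, some members passed. Of the 32 members, 5 fell when adjusted over the list alone and 0 over all genes. They included the receptor for double-stranded RNA TLR3 (-1.84 ± 0.89), the adhesion molecule gene ICAM1 (-0.90 ± 0.38), the NF-kB inhibitor gene NFKBIA (-0.63 ± 0.33) and the kinase gene IRAK2 (-0.57 ± 0.03). The list passed camera with the preset correlation (adjusted p = 3.84e-09), but not fry (adjusted p = 0.0947) and not camera otherwise (adjusted p = 0.113 with an estimated correlation).

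Proliferation genes were higher with long telomeres in the PC-3 pairs, with medians of 0.90 in the PC-3 pair and 1.11 in the PC-3/cre pair, and of smaller size in the HBC4 pair (0.08) and the MKN74 pair (0.04). The medians lay above 100%, 100%, 94.8% and 97.4% of the random lists in the PC-3, PC-3/cre, HBC4 and MKN74 pairs, a placing that is no test. Of the 40 members, 14 were higher, and 0 lower, in all 4 pairs. Over all pairs the 40 tested members had a median log2 ratio of 0.52. None of the 40 passed limma over all genes or adjusted over the list alone (0 and 0). The proliferation marker MKI67 had a mean ratio of 0.62 ± 0.41, the kinesin gene KIF11 one of 0.70 ± 0.50, the topoisomerase gene TOP2A one of 0.58 ± 0.46 and the spindle checkpoint kinase gene BUB1B one of 0.54 ± 0.33. The list passed camera with the preset correlation (adjusted p = 1.49e-16) and not fry (adjusted p = 0.39). Its members varied together (estimated correlation 0.869), and camera gave an adjusted p = 0.429 with an estimated correlation. In the PC-3 pairs, the 5' to 3' difference of control transcripts also differed between the arms, by 0.28 and 0.20 (long minus short), against 0.05 in the HBC4 pair and -0.06 in the MKN74 pair.

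Smaller list shifts passed camera with the preset correlation and no other list test. Genes of the endoplasmic reticulum stress response had a median of -0.24 (adjusted p = 3.5e-05; adjusted p = 0.208 with an estimated correlation), among them DDIT3 at -0.60 ± 0.29 and the chaperone gene HSPA5 at -0.45 ± 0.29. Hypoxia and glycolysis genes had a median of 0.18 (camera adjusted p = 0.000273; adjusted p = 0.25 with an estimated correlation), with the pyruvate dehydrogenase kinase gene PDK1 at 0.60 ± 0.32. Fibroblast markers had a median of 0.20 (camera adjusted p = 0.0214; adjusted p = 0.429 with an estimated correlation), with COL1A1 at 0.65 ± 0.91. Epithelial genes had a median of -0.13 (camera adjusted p = 0.0305; adjusted p = 0.512 with an estimated correlation), with the tight junction gene OCLN at -0.69 ± 0.81 and the desmosomal cadherin DSC2 at 0.84 ± 1.05. In these 4 lists 0 members passed limma over all genes and 0 when adjusted over the list alone.

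The remaining lists did not pass camera. Mesenchymal genes had a median of 0.08 (adjusted p = 0.0941), with FN1 at 0.70 ± 0.55 and the lysyl oxidase gene LOX at -1.34 ± 1.54. Telomerase and telomere-binding genes other than TERT had small ratios, such as MRE11 at 0.38 ± 0.28 and TERF1 at -0.25 ± 0.16, and the list with TERT had a median of 0.09 (camera adjusted p = 0.433). Medians were 0.02 for p53 target genes, with SESN2 at -0.40 ± 0.13, and 0.06 for glandular and secretory genes, with TFF1 at 1.30 ± 1.23 (camera adjusted p = 0.863 for both). They were 0.03 for integrins and matrix adhesion genes (camera adjusted p = 0.742), with ITGA10 at -0.59 ± 0.21, and 0.06 for endothelial markers (camera adjusted p = 0.708), with KDR at -0.81 ± 0.77. No member of these lists passed limma over all genes or adjusted over the list alone (0 and 0).

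Leukocyte markers had a median log2 ratio of -0.05 over 15 tested members (camera adjusted p = 0.405), although host cells are of mouse and the probes of human sequence. Of them 0 passed over all genes and 1, S100A8, rose when adjusted over the list alone, while its partner S100A9 had a ratio of -0.74 ± 0.90. Among blood, muscle and fat markers, which included keratins of skin, KRT14 rose over all genes and adjusted over the list alone (1 and 1), and the adipocyte gene FABP4 had a ratio of 1.70 ± 1.73. The median of that list was -0.04 and its mean 0.10, with camera directed downward (adjusted p = 0.863) and fry upward (adjusted p = 0.505).

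**Figure D2:**
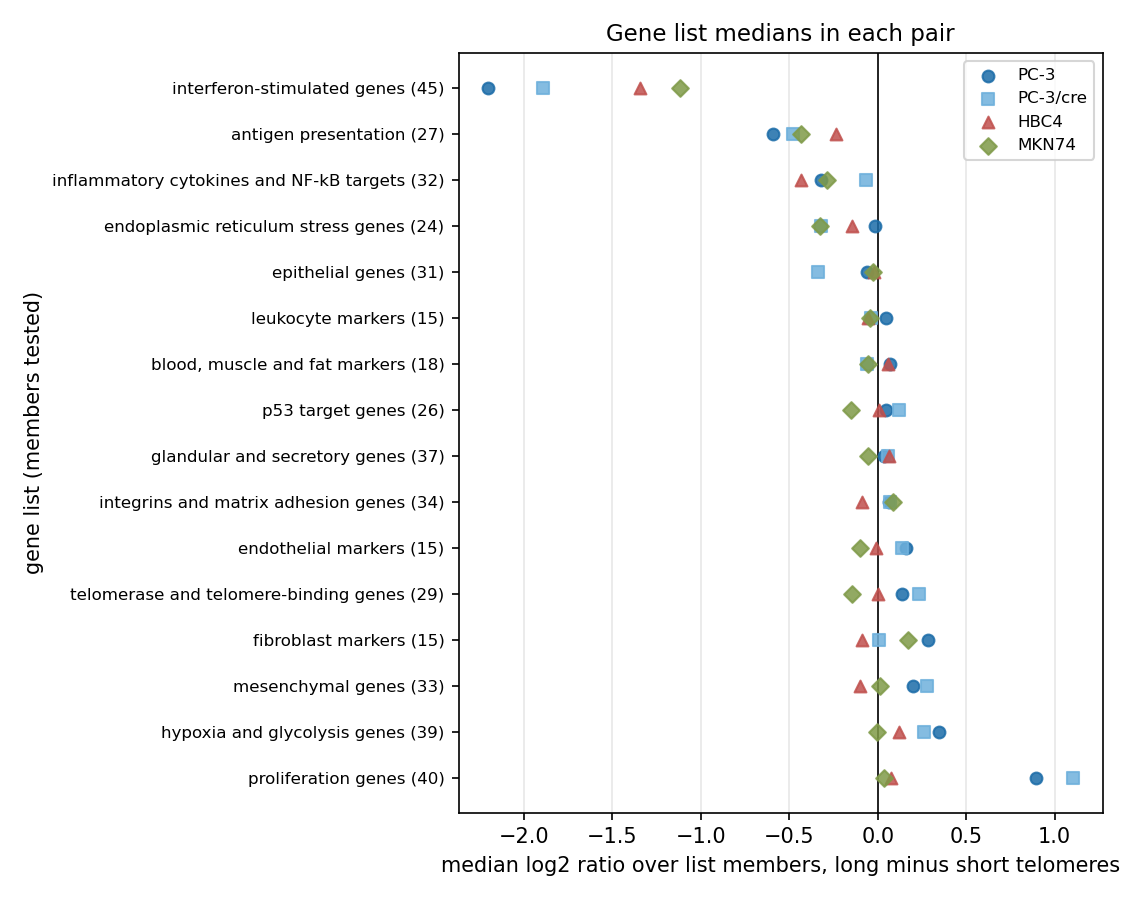
Median log2 ratio of long over short telomeres (horizontal axis) of the 16 gene lists (vertical axis, with the number of members tested), 1 symbol per pair. Interferon-stimulated genes lie between -2.20 and -1.12 in the 4 pairs, and proliferation genes lie at 0.90 and 1.11 in the PC-3 pairs and at 0.08 and 0.04 in the HBC4 and MKN74 pairs.

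Within single pairs, more genes differed in the PC-3 background than in the other lines. At 2-fold, 399 genes were higher and 315 lower in the PC-3 pair, and 666 were higher and 806 lower in the PC-3/cre pair. The HBC4 pair had 52 higher and 147 lower genes, and the MKN74 pair 79 higher and 138 lower ones. These are sizes without a test, since each arm is 1 array, and the counts were smaller when the probe sets of a gene were averaged. In the PC-3 pair the lowest ratios were those of XAF1 (-3.79), the death ligand gene TNFSF10 (-3.42), CLTRN (-3.26) and GBP4 (-3.18), and the highest those of EPB41L3 (5.37), SCN3A (4.41), FABP4 (3.93) and RTN1 (3.69). In the PC-3/cre pair the lowest ratios were those of CDC20B (-4.79), the fibrinogen chain genes FGB (-4.48) and FGG (-3.97), and TNFSF10 (-3.53). The highest in that pair were EPB41L3 (5.79), the steroid dehydrogenase gene HSD17B2 (5.69), the ephrin receptor gene EPHA5 (4.78) and the hyaluronan synthase gene HAS2 (4.77).

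In the HBC4 pair the lowest ratios were those of IFI6 (-4.60), IFI44L (-4.33), IFIT1 (-3.66) and the matrix protein gene POSTN (-3.46). The highest were PCDH9 (3.87), TERT (3.76), C8orf48 (3.08) and the water channel gene AQP1 (2.71). In the MKN74 pair the lowest ratios were those of IFI44L (-3.66), IFI44 (-3.49), TM4SF18 (-3.42) and RSAD2 (-2.80), and the highest those of TERT (4.77), the chemokine gene CXCL14 (1.84), CYRIA (1.76) and TTC22 (1.75).

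The ratios of long over short telomeres were compared between the PC-3 pairs and the other lines. Whether differences stem from telomere length or from passage or clonal differences was not tested. EPB41L3, which encodes a membrane skeleton protein, had a mean log2 ratio of 5.58 in the PC-3 pairs and 0.15 in the others, a difference of 5.43 ± 0.23 (SE; limma adjusted p = 0.00249). Of the 4 genes with the smallest p in that direction, the sodium channel gene SCN3A (difference 4.25), ZPLD1 (3.70) and the interstitial collagenase gene MMP1 (2.87) were also above, at limma adjusted p-values of 0.0102, 0.0147 and 0.0147. MMP1 had a mean of 1.96 in the PC-3 pairs and -0.91 in the others. The 4 with the smallest p in the other direction, the semaphorin gene SEMA6D (difference -2.17), DPY19L2 (-2.56), the receptor gene IL18R1 (-1.91) and CLIP4 (-1.94), were below, at limma adjusted p-values of 0.03, 0.0343, 0.0428 and 0.0428.

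In total 62 genes differed between the PC-3 pairs and the others at a limma adjusted p of 0.05, with the PC-3 ratio above in 39 and below in 23. There were 3 members of the interferon list among them (IFIH1, PLSCR1 and TRIM22) and 1 of the proliferation list (CDC6). The interferon list had medians of -2.12 in the PC-3 pairs and -1.13 in the others, and the proliferation list medians of 1.00 and 0.04. Both differences passed camera with the preset correlation, a test added after the data were seen (adjusted p = 5.83e-10 and 2.2e-20), as did that of antigen presentation (adjusted p = 0.0364), and all 3 had an adjusted p = 0.691 with an estimated correlation. The 5' to 3' shift of control transcripts followed the same split, at 0.28 (PC-3), 0.20 (PC-3/cre), 0.05 (HBC4) and -0.06 (MKN74). Its part in the interferon difference was not tested. The other 2 ways to set 2 pairs against 2 gave 0 genes each in limma. Both ways separate the PC-3 pairs, so changes that these pairs share add to the residual spread. The 0 counts therefore give no support to the 62 genes. The count depended on the setting: with each array centred on its median it was 11, with 10 above and 1 below, and without single pairs it ranged from 0 (without HBC4) and 2 (without MKN74) to 167 (without PC-3/cre) and 957 (without PC-3), where 1 side held a single pair.

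The PC-3 and PC-3/cre pairs differ in that the long-telomere cells over-express hTERT in the former and have basal hTERT in the latter, with separate control arrays. Across genes their log2 ratios had a Pearson correlation of 0.657, against -0.0821 to 0.131 between the other combinations of pairs. Genes at least 2-fold higher in both numbered 221, against 13.4 for independent lists, and genes at least 2-fold lower in both numbered 213, against 12.8, while 14 went opposite ways. Without the interferon list the correlation was 0.645. Of the interferon list, 44 of 45 members were lower in both PC-3 pairs, and the ratio of the PC-3 pair minus that of the PC-3/cre pair had a median of -0.24 (quartiles -0.55 and 0.12). Genes are not independent replicates, and no test was run, since each arm held 1 array. The titles do not state how the long-telomere cells of the PC-3 and PC-3/cre pairs were derived. The submitters' design text relates these cells to each other by name, so these pairs may not be independent. Both pairs also had a 5' to 3' shift of control transcripts (0.28 and 0.20, long minus short).

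**Figure D3:**
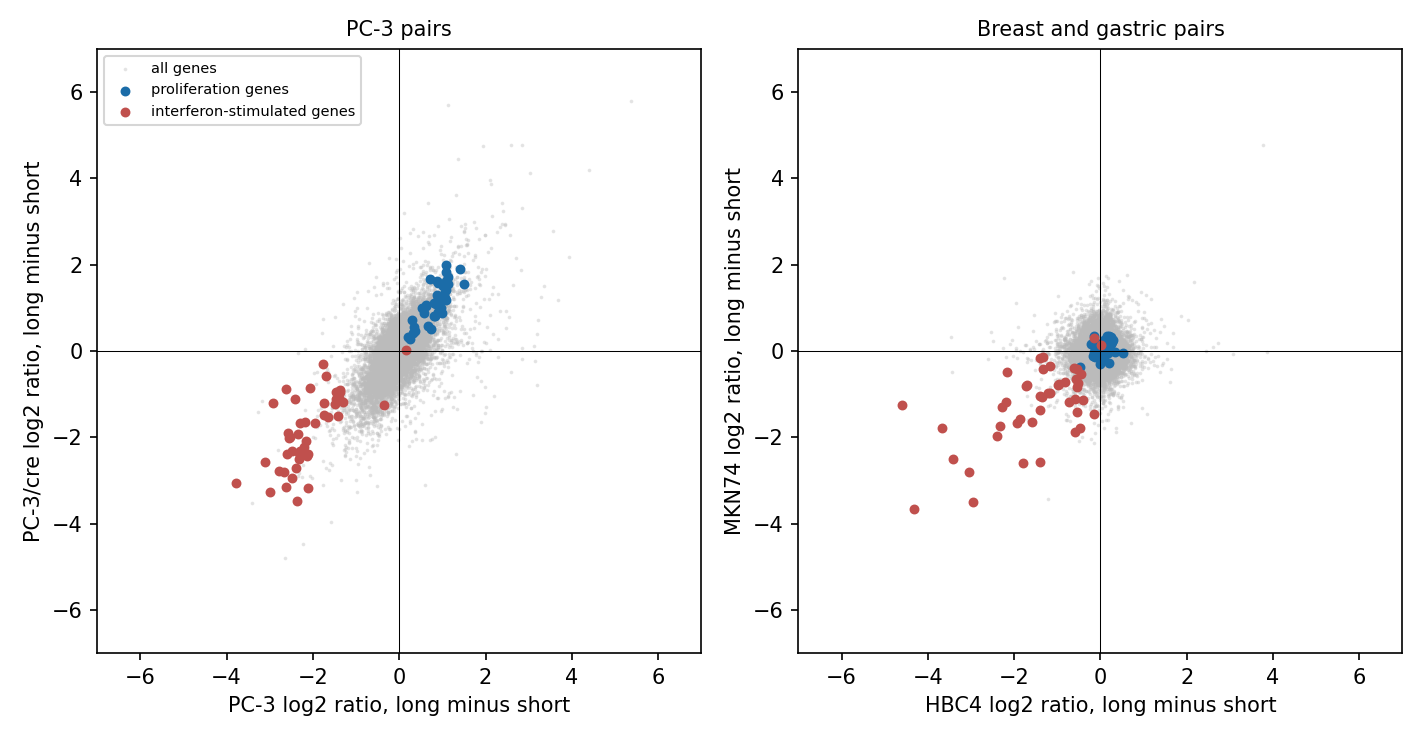
Log2 ratios of long over short telomeres for each gene (grey points) in the PC-3/cre pair against the PC-3 pair (left panel) and in the MKN74 pair against the HBC4 pair (right panel), with proliferation genes in blue and interferon-stimulated genes in red. The correlation across genes is 0.657 in the left panel and 0.0998 in the right panel.

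Genes near chromosome ends were examined because telomere length could act on them. The 820 genes that were among the 20 measured genes nearest to an end, over 41 ends, had a median log2 ratio of 0.0139, against 0.012 for all genes. None passed limma over all genes (0), and limma's camera gave an adjusted p = 0.989 with the preset correlation and an adjusted p = 0.995 with an estimated correlation (1 set in the family, so the adjustment leaves the value unchanged). Among the 50 genes changed in all 4 pairs, 4 lay in this set (CIMAP1B, IFITM1, ISG15 and TLR3), against 2.07 by chance.

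Array pairs of the breast and gastric lines were alike, with correlations over all probe sets of 0.938 for HBC4 and 0.918 for MKN74. The PC-3 arrays were less alike within a pair, at 0.642 for PC-3 and 0.450 for PC-3/cre. Centring over all arrays, among which PC-3 is the most frequent line, can remove much of that line's own profile and so lower these correlations. The SD over all probe sets was 0.46 to 0.53 in the PC-3 arrays and 0.74 to 0.77 in the others. Each PC-3 array was nearest to the PC-3 array of the other pair with the same telomere state, with correlations of 0.850 between the long-telomere arrays and 0.798 between the short-telomere arrays. No array was a copy of another.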

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

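The tests of labelling yield, host leukocytes, hTERT over-expression, degraded RNA and skin, and the sign patterns for the interferon median and the 1.5-fold count, were chosen after the results were seen, and the bounds for leukocytes, degraded RNA and skin were revised once their values were known. The sign patterns for the limma count and the splits of pairs between lines were fixed before.

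The fall of interferon-stimulated genes in all 4 pairs is the pattern most worth a closer look. The poly-A spike controls, outside the comparisons of the report, were higher in the long-telomere array by 0.49 in the PC-3 pair, 0.64 in the PC-3/cre pair and 0.50 in the MKN74 pair, but differed by only -0.01 in the HBC4 pair, where the interferon median was still -1.34, which argues against labelling yield as the whole cause. Over-expressed hTERT at the time of sampling as the whole cause is argued against by the PC-3/cre pair, labelled as having basal hTERT, where the median was -1.89, although TERT was still 1.73-fold higher there. Fewer host leukocytes stay open: the leukocyte median was -0.0468, but mouse RNA was not shown to reach these human probes, so the 2 cannot be told apart. Telomere length itself, passage and clonal differences between the cell lines were not tested and may each contribute.

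For the interferon list, the labelled direction of the pairs gave the largest absolute median among the 8 sign patterns (1 of 8, the highest other was 1.02). The list median was already negative in all 4 pairs, so flipping any pair had to shrink it. This rank restates the pattern and does not test it. Over all genes tested, the labelled direction also gave the most genes past the limma threshold (9, 1 of 8, the highest other was 0). The same was true of genes changed 1.5-fold in all 4 pairs (50, 1 of 8, the highest other was 6). With 8 patterns no share under 0.05 can be reached. Among 24 splits of the arrays that part only 2 pairs, the 2 that part both PC-3 pairs as labelled and leave the other pairs whole gave 1881 genes, which points to a structure shared by the PC-3 arrays. With the pair as a block, the side given to a whole pair does not change the fit. These 2 splits are therefore 1 fit, and the others repeat each other likewise. The other 22 gave 0, and 3 splits part no pair. In those 22 the changes shared by the PC-3 pairs count as residual spread, so their 0 counts add no support.

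Ratios differed between the PC-3 pairs and the other lines for 62 genes by limma, in 1 of 3 splits of the pairs into 2 and 2. The highest other count was 0, and 3 splits cannot give a share under 0.05. The other splits separate the PC-3 pairs, so changes that these pairs share add to the residual spread there, and the 0 gives no support. The 4 differences with the smallest p in each direction were 5.43 for EPB41L3, 4.25 for SCN3A, 3.70 for ZPLD1, 2.87 for MMP1 (PC-3 above), and -2.17 for SEMA6D, -2.56 for DPY19L2, -1.91 for IL18R1 and -1.94 for CLIP4 (PC-3 below).

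Proliferation genes were higher with long telomeres in the PC-3 pairs and less so in the others, a difference that did not pass camera with an estimated correlation. Labelling yield is argued against by the MKN74 pair, whose spike difference was like that of the PC-3 pair while its proliferation median was 0.0365. More degraded RNA in the short-telomere PC-3 arrays may contribute, since the control transcripts shifted in both PC-3 pairs. The shift was lower in the PC-3/cre pair than in the PC-3 pair (difference -0.0803), although the PC-3/cre proliferation median was higher. The 2 control transcripts gave -0.119 and -0.0421 for this difference. It lies within the SD of the shift over the 4 pairs (0.15). That SD includes the gap between the PC-3 pairs and the others, so it does not measure the error of a shift and decides nothing. Degraded RNA, growth of the tumours at sampling and selection in the PC-3 cells cannot be told apart with 1 array per arm.

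KRT14, S100A8 and CLCA2, which basal or stressed epidermis expresses, were higher in the long-telomere array of all 4 pairs, with skin in the samples as a candidate source. The other 24 epidermal markers tested had medians of 0.14, 0.12, -0.08 and 0.52 in the PC-3, PC-3/cre, HBC4 and MKN74 pairs, with upper quartiles of 0.31, 0.36, 0.13 and 0.97, while the lowest of the 3 genes stood at 1.14, 0.79, 0.65 and 1.21. The first 3 pairs thus go against skin and the MKN74 pair does not. Host skin is of mouse, and which of its transcripts reach human probes is unknown, so skin and a change in the tumour cells cannot be told apart.

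List medians that stood apart from those of the other pairs were -0.34 for epithelial genes in the PC-3/cre pair, -0.0914 for integrins and matrix adhesion genes in the HBC4 pair and 0.0465 for leukocyte markers in the PC-3 pair. They were 3 of 42 groups of 4 values examined, and about 1 in 20 such groups stands apart by chance. Among 13522 probe sets without a single gene symbol, 4 were at least 1.5-fold lower and 1 higher in all 4 pairs, against at most 4 in total under another sign pattern.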

How the results depend on the processing

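Filters on the spread of the pair means, the trend in the moderation and the cell line as a block were chosen after seeing the data. The TERT ratio turned negative in the PC-3 and MKN74 pairs on the other probe set (-0.39 and -0.05). Not run were the percentile filter on mean levels, the probe set with the highest mean, repeated quantile normalization and a trend on the mean level, since centred values hold no levels and signal over background is unknown.

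Without the pair as a block, limma gave 0 genes for long against short telomeres (109 at an unadjusted p under 0.05), and with the pairing as a random block also 0 (1437 unadjusted). It gave 1 gene with the PC-3 pairs averaged (731 unadjusted), 14 with a trend, robust or not (7 shared with the 9), and 0 to 3 without single pairs. With the cell line as the block it gave 8, of which 6 were shared.

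The 1.5-fold count was 21 at 2-fold and 210 at 1.2-fold, and 56 to 118 without single pairs. The count between PC-3 and other lines was 13 and 4 with filters at the 40th and 60th percentile of spread, 11 with centred arrays, 229 with a trend, 253 when robust, and 0 to 957 without single pairs. The cause of these moves was not tested.

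With averaged probe sets, 2-fold counts were 232 higher and 188 lower (PC-3), 454 and 412 (PC-3/cre), 27 and 84 (HBC4) and 24 and 81 (MKN74). The PC-3 correlation was 0.684 with either filter (0.6841 and 0.6839) and 0.564 as Spearman. The other TERT probe set gave a mean of 0.14.

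For lists, camera with an estimated correlation gave adjusted p = 0.113 for interferon, antigen presentation and cytokine genes, 0.512 for epithelial, 0.429 for proliferation, 0.25 for hypoxia, 0.208 for stress and 0.429 for fibroblast genes. Fry gave 0.0947 for cytokines, 0.505 for epithelial, 0.39 for proliferation, 0.112 for hypoxia, 0.114 for stress and 0.505 for fibroblast genes. Epithelial genes gave camera adjusted p-values of 0.106 and 0.0966 with the filters, 0.207 with no block for the pair and 0.116 with a random block. Fibroblast markers gave 0.0825 and 0.0966 with the filters, hypoxia genes 0.0807 with no block, and mesenchymal genes 0.0429 with averaged probe sets. Without single pairs, camera adjusted p-values ranged from 0.00444 to 0.664 for epithelial genes, from 0.00337 to 0.38 for mesenchymal genes and from 0.00054 to 0.391 for fibroblast markers.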

Other observations

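The lists described here were written and tested after the values had been seen. Detection is not known from centred values, so a ratio near 0 does not show that a gene was expressed and unchanged. Interferon of the host is of mouse, and mouse RNA was not shown to reach these human probes. Genes of the interferons themselves did not pass camera (adjusted p = 0.916): 18 tested members had a median log2 ratio of 0.0293 (quartiles -0.0474 and 0.0425), with IFNB1 at -0.20 ± 0.50 (SD, n = 4 pairs) and IFNL1 at -0.20 ± 0.26, and 0 passed limma over all genes or adjusted over the list alone. The 9 interferon receptors and kinases had a median of -0.28, with IFNAR1 at -0.28 ± 0.09 and the kinase gene JAK2 at -0.76 ± 0.64, and 0 passed either way. That list passed camera over the 3 lists with the preset correlation (adjusted p = 0.000135) and fry (adjusted p = 0.049), with an adjusted p = 0.0776 with an estimated correlation.

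Nucleic acid sensors and their adaptors went both ways. Their median was -0.18 over 17 tested members, with TLR3 at -1.84 ± 0.89 and IFIH1 at -1.88 ± 1.18 against CGAS at 0.57 ± 0.81 and MAVS at 0.24 ± 0.20. Of them 2 passed limma adjusted over the list alone and 0 over all genes. The list passed camera (adjusted p = 0.0354) and fry (adjusted p = 0.00743), with an adjusted p = 0.139 with an estimated correlation, and it shares IFIH1, RIGI and TLR3 with the lists fixed beforehand.

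That telomere length acts on genes near chromosome ends was a hypothesis written before its result was seen. The set of genes nearest to the ends did not pass as a group (camera in limma, adjusted p = 0.989; the alternatives ranged from 0.204 to 0.995, and with 1 set in the family the adjustment leaves the value unchanged), which argues against a common shift of that set and says nothing about single genes.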
